A study of Mus musculus with 6 samples.

How the data were processed

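Total RNA was extracted from intestine with TRIzol, depleted of ribosomal RNA, made into libraries with a directional kit and sequenced on a BGISEQ-500, per the labels' protocols. The submitters' processing notes name fastp 0.20.0, Bowtie2 2.3.1 and eXpress 1.5.1 and the build mm10, and do not give the role of each. The annotation release is not given in the sources used here. The authors deposited 1 table per library with gene ID, transcript IDs, length, expected count and FPKM, per the file headers. The deposited expected counts are estimated fragment counts per gene that are not normalized. They were whole, within 1e-09, in all libraries for 65.6% of genes. The deposited FPKM values are scaled by gene length and by a library total. The ratio of count to FPKM was linear in length within each library, and it gave a library total of 681696 to 4574309, of which the listed counts made up 23.2% to 28.8%. What else that total counts is not given in the sources used here. Only genes with an estimate above 0 were listed, and an unlisted gene was taken as 0.

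All IDs belong to a single series of noncoding gene IDs, and 0 of the 25228 matched the gene name and RefSeq tables used for symbols. The 59 gene lists fixed before the data were examined are lists of symbols, so 0 of them had a member among the IDs, and the tests of these lists and the genes to be named from them were not run. Strand use in counting is not given in the sources used here, so overlapping and antisense gene models may share reads, and genes with counts that are not whole are uncertain for that reason.

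Expected counts were rounded and the 6 libraries were fitted in 1 model with a mean per group, without a replicate block, in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 7316, and libraries were scaled by TMM. The quasi-likelihood test was applied to 3 contrasts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 3 groups of 2 libraries share 3 residual degrees of freedom, and the common biological coefficient of variation was 27.8%. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use the TMM-scaled totals, except the floors given per library for the listed totals. A fold against a group whose libraries were all at 0 was computed against a floor of 3 counts per library, averaged over the group, as a lower bound.

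The rule for the genes named was written before the data were examined. It took the largest absolute log2 fold changes, per direction, among genes with an adjusted p under 0.05, a mean log2 CPM at or above the median of tested genes and no overlap between the libraries of the 2 groups. The order uses fitted log2 fold changes, also for genes at 0 throughout a group, whose bounds can lie below the folds of genes that are not named. The part of the rule that asks for a symbol could not be applied. In db-CLP against db-sham 229 higher and 183 lower genes qualified, and in db-CLP against wt-CLP 148 and 109 did. Since no table pairs the IDs with names, the first 2 per direction are named. The third contrast is given as counts.

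The procedure was tested on simulated data with 200 of 7316 genes changed in 1 group at the depths of these libraries. For db-CLP against db-sham the edgeR test recovered 0% of genes changed 2-fold (DESeq2 3%, limma 0%), 49.5% of those changed 4-fold and 79% of those changed 8-fold. For db-CLP against wt-CLP with db-CLP changed it recovered 0% (DESeq2 2.5%, limma 0%), 52% and 83%. For wt-CLP against db-sham it recovered 3%, 50.5% and 81%. In 20 simulated sets of unchanged libraries the 3 contrasts gave 0.8, 1.4 and 0.8 calls on average, and at most 3, 6 and 4.

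Classes of genes by number of transcripts, length, ID version and whole counts were chosen after seeing the data. They were tested for how often they were called by Fisher's exact test and, within 10 strata of abundance, by the Mantel-Haenszel test, for the direction of the called members by Fisher's exact test, and for a shift by camera from limma 3.58.1. Overlaps of calls between contrasts that share libraries were set beside 20 simulated sets of unchanged libraries and beside n1 × n2 / N. The correlation with a different db-CLP library in each comparison was added after seeing the data.

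Alternatives were other scaling factors (RLE, upper quartile), no filter and a filter of 50 counts in 2 libraries, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 1 and 0.1, the 4 libraries compared alone, a replicate block, a robust fit, a 2-fold minimum and leaving out each library. Scaling to the implied library totals, thinning all libraries to 196251 counts and keeping only genes with whole counts were added after seeing the data. Numbers were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.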

Results

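The series profiled total RNA of mouse intestine in 3 groups of 2 libraries. The wt-CLP and db-CLP groups underwent CLP, the usual abbreviation of caecal ligation and puncture, an operation that causes sepsis from gut bacteria. The db-sham group had a sham operation, and the series title calls the mice diabetic and septic, with db and wt given as disease states. The files listed 25228 gene IDs with an estimate above 0 in at least 1 library, and 7897 of these were listed in all 6. Every ID carried the prefix that the NONCODE database of noncoding RNA genes uses for mouse, and none was paired with a symbol or a position.

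The total of estimated counts was 1100216 in wt-CLP replicate 1, 940409 in wt-CLP replicate 2, 1062340 in db-CLP replicate 1, 770016 in db-CLP replicate 2, 196258 in db-sham replicate 1 and 957360 in db-sham replicate 2. The listed genes made up 27.8% ± 0.837 (SD, n = 2) of the library total implied by the FPKM values in wt-CLP, 23.6% ± 0.498 in db-CLP and 26.8% ± 2.83 in db-sham. This share differed between db-CLP and wt-CLP with a two-sided exact permutation p of 0.3333, the smallest that 2 libraries against 2 can give. A count of 3, the upper limit that 0 counts allow, stood for 15.3 CPM (counts scaled to a common library size) in db-sham replicate 1 and for 2.73 to 3.90 CPM in the other 5 libraries. The 5 most abundant genes of a library took the lowest share of its counts in db-sham replicate 2, 11.9%, and the highest in db-CLP replicate 2, 29.7%. Across genes, which are not independent replicates, log2 CPM correlated within groups at 0.932 in wt-CLP, 0.891 in db-CLP and 0.859 in db-sham, and between groups at 0.754 to 0.885. The library db-sham replicate 2 correlated more with wt-CLP replicates 1 and 2, at 0.869 and 0.885, than with its own replicate. For the shallower db-sham replicate 1 the highest correlation was with its own replicate, against 0.807 and 0.810 with wt-CLP and 0.761 and 0.754 with db-CLP. By this measure replicate 1 was thus closest to its own group and replicate 2 to wt-CLP, which bears on both comparisons with db-sham.

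**Figure D1:**
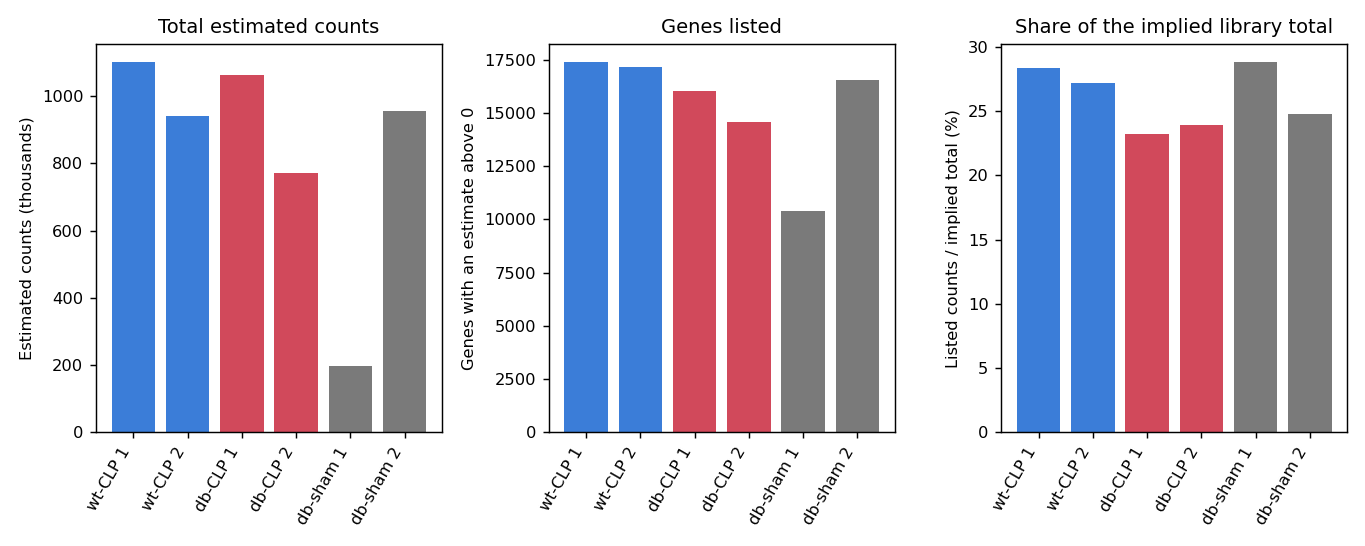
Total estimated counts, number of genes listed and the listed share of the implied library total in percent, with 1 bar per library. The library db-sham replicate 1 held 196258 counts and 10387 genes, the lowest of the 6 on both measures.

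The first comparison, db-CLP against db-sham, asked which intestinal noncoding genes differ after CLP within the db mice. Of 7316 genes tested, 272 were higher and 242 were lower in db-CLP. NONMMUG014782.2 was at 178 ± 8.50 CPM (SD, n = 2) in db-CLP and at 0 in both db-sham libraries, which made it at least 19.7-fold higher against a floor of 3 counts per library. NONMMUG013433.2 was at 54.9 ± 17.2 CPM in db-CLP and at 0 in both db-sham libraries, at least 6.07-fold higher. These bounds became 62.1-fold and 19.1-fold without db-sham replicate 1, and 11.7-fold and 3.61-fold without db-sham replicate 2. In the other direction, NONMMUG038962.2 fell from 909 ± 324 CPM in db-sham to 23.2 ± 16.0 CPM in db-CLP, a log2 fold change of -5.41 (SE 0.446) that became -4.70 without db-CLP replicate 1 and -6.24 without db-CLP replicate 2. NONMMUG022015.2 fell from 184 ± 66.4 CPM to 4.10 ± 5.80 CPM, a log2 fold change of -5.81 (SE 0.813). It became -4.49 without db-CLP replicate 1 and a fitted -10.35 without db-CLP replicate 2, when the remaining db-CLP library held 0 counts and the fitted value is no bound.

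The counts of NONMMUG013433.2 and NONMMUG038962.2 were not whole in some library, so their values are uncertain where reads were split between gene models. The 4 genes named for this comparison had adjusted p of 3.02e-04, 0.00184, 7.07e-05 and 0.00180 in the order in which they were named, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The median absolute log2 fold change of the 514 genes called was 2.10 with the 29 genes that were at 0 throughout a group set to their bound, and 2.20 as fitted. Over all genes tested, the values of the 2 groups did not overlap for 48.7%, where chance separates 33.3%. Scaled to the library totals implied by the FPKM values, the median gene moved by -0.40 on the log2 scale and 725 genes were called, 171 higher and 554 lower. The directions above are therefore relative to the median listed gene. The edgeR count was 191 without db-sham replicate 1 and 57 without db-sham replicate 2, with the remaining sham library assumed to vary like the other groups, and limma on log2(FPKM + 1) called 202 genes (61 higher, 141 lower). Without db-sham replicate 2, NONMMUG013433.2 and NONMMUG022015.2 did not pass by edgeR (adjusted p of 0.0840 and 0.0787, with ranges over the alternatives of 2.75e-09 to 0.0840 and 3.47e-19 to 0.167).

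Of 5 classes of genes formed from what the files give, 3 differed in how often genes were called and the 2 length classes did not pass the test. These tests take genes as independent units, which they are not, so their p-values do not measure replication over mice. A lower share of calls can come from less precise counts or from fewer changes, and the 2 were not separated. Genes with more than 1 transcript were called in 9.47% of cases and genes with 1 transcript in 5.95% (Fisher's exact test, adjusted p = 3.07e-07 over 10 tests). Within 10 strata of mean abundance the odds ratio of this class was 1.57 (Mantel-Haenszel test, adjusted p = 9.05e-06). Genes whose ID ends in version 1 were called in 4.79% of cases, against 8.32% of the others (adjusted p = 1.96e-08 by Fisher's exact test). Genes with counts that were not whole in some library, as estimates that split reads between gene models give, were called in 4.68% of cases, against 9.57% of the genes with whole counts (adjusted p = 2.05e-15 by Fisher's exact test). Genes under 1000 bases were called in 6.63% of cases against 7.16% (adjusted p = 0.547), and genes of 3000 bases or more in 7.53% against 6.90% (adjusted p = 0.493), both by Fisher's exact test. None of the 5 classes shifted in 1 direction by camera, where the lowest adjusted p was 0.876 with the preset correlation and 0.964 with an estimated correlation, although edgeR called 85 version 1 genes higher and 43 lower, against 187 and 199 of the others (Fisher's exact test on direction, adjusted p = 0.00490 over 10 tests). Scaled to the implied library totals, the called version 1 genes were 54 higher and 121 lower, and the others 117 and 433. Of the called multi-transcript genes 108 were higher and 103 lower.

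**Figure D2:**
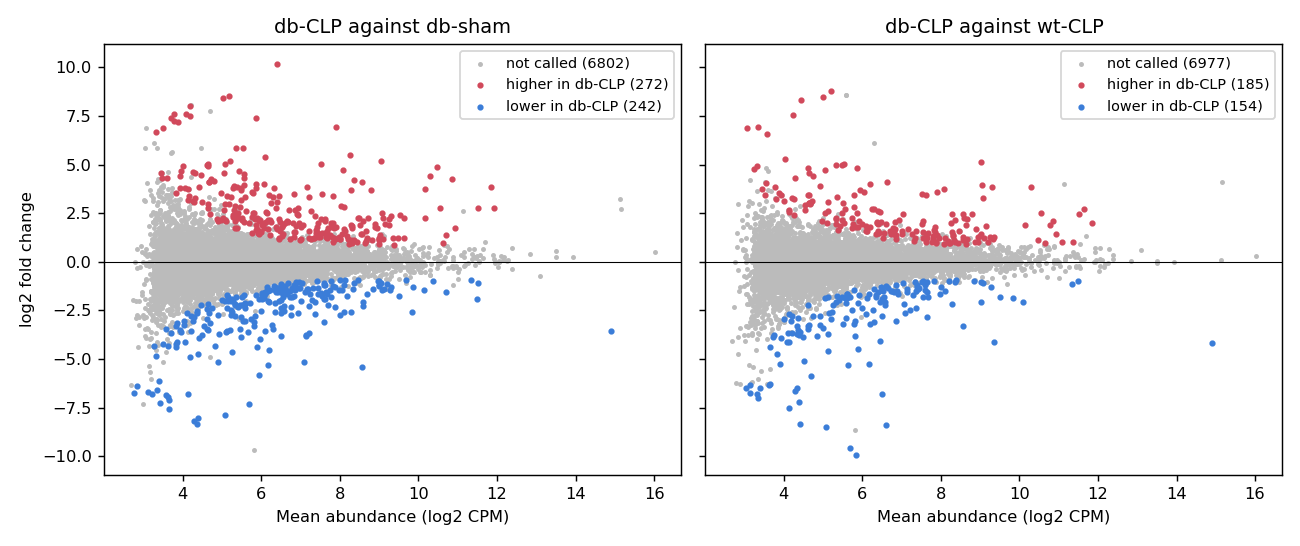
Log2 fold change against mean abundance in log2 CPM for the 7316 genes tested, with 1 point per gene, in both comparisons of db-CLP. Against db-sham 272 genes were higher and 242 lower, and against wt-CLP 185 were higher and 154 lower.

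The second comparison, db-CLP against wt-CLP, held the operation fixed and asked which genes differ with the disease state. It gave 185 genes that were higher and 154 that were lower in db-CLP. NONMMUG073606.1 was at 67.7 ± 0.515 CPM in db-CLP (SD, n = 2) and at 0 in both wt-CLP libraries, at least 23.0-fold higher, and NONMMUG014452.2 was at 53.9 ± 12.04 CPM against 0, at least 18.3-fold higher. Both were also present in db-sham, at 41.5 ± 5.85 and 37.1 ± 16.6 CPM. NONMMUG013301.2 was at 150 ± 77.8 CPM in wt-CLP and at 0 in both db-CLP libraries, at least 38.1-fold lower in db-CLP, and was at 0 in both db-sham libraries as well. NONMMUG041052.2 was at 117 ± 55.3 CPM in wt-CLP and at 0 in both db-CLP libraries, at least 29.7-fold lower, while its db-sham libraries held 0 and 33.5 CPM. The counts of NONMMUG041052.2 were not whole in some library, so its values carry the same uncertainty. Without wt-CLP replicate 1 the last 2 bounds became 24.1-fold and 19.8-fold.

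By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 4 genes was 5.52e-04, 0.00120, 7.62e-04 and 0.00357. The median absolute log2 fold change of the 339 genes called was 2.07 with the 23 genes at 0 throughout a group set to their bound, and 2.10 as fitted. Over all genes tested, the 2 groups did not overlap for 48.5% (chance, 33.3%). Multi-transcript genes were again called more often than the rest, in 6.29% against 3.91% of cases (Fisher's exact test, adjusted p = 3.25e-05). Scaled to the implied library totals, the median gene moved by -0.43 on the log2 scale and 487 genes were called, 98 higher and 389 lower. The edgeR count was 223 without wt-CLP replicate 1, 126 without wt-CLP replicate 2 and 206 without db-sham replicate 1, and limma on log2(FPKM + 1) called 39 genes (10 higher, 29 lower). With DESeq2, NONMMUG013301.2 and NONMMUG041052.2 did not pass (adjusted p of 0.450 and 0.0821, with ranges over the alternatives of 3.84e-23 to 0.450 and 5.89e-20 to 0.222).

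**Figure D3:**
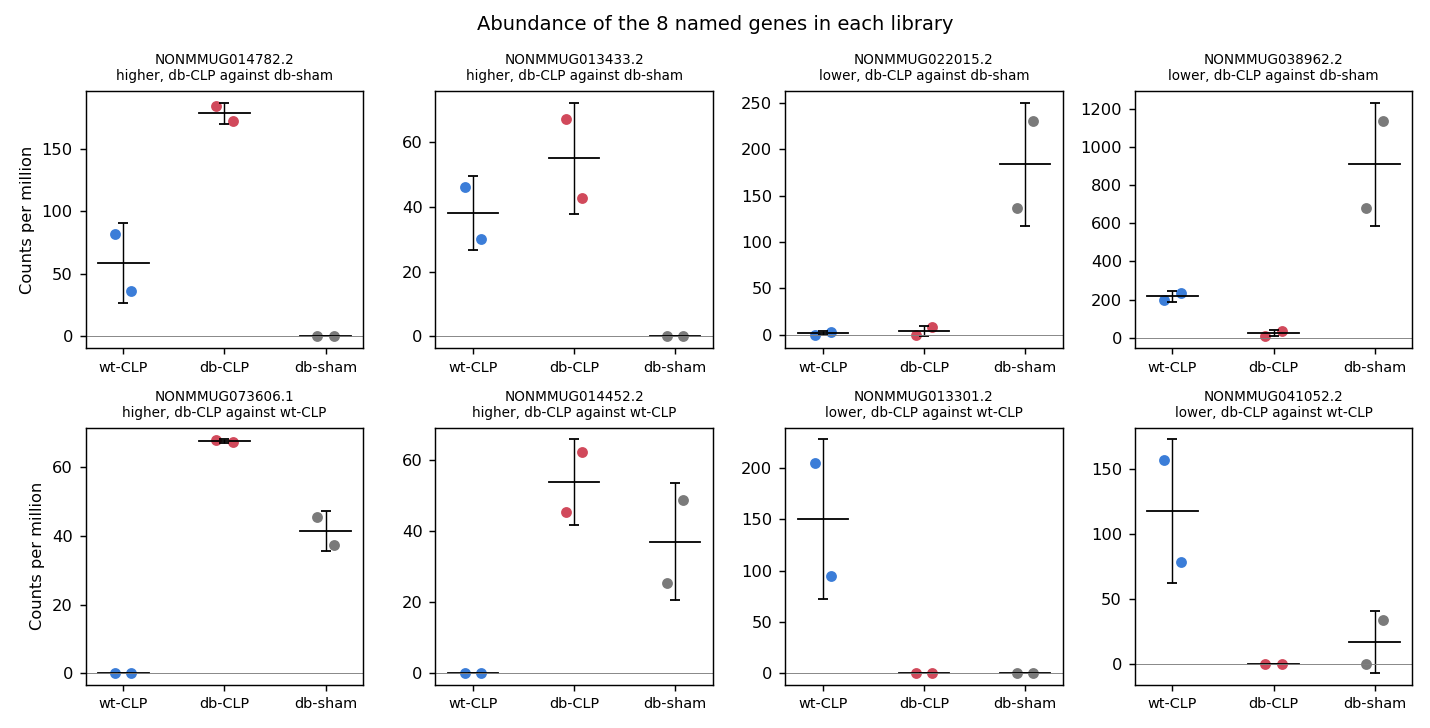
Abundance in CPM in each library for the 8 genes named by the rule, with points for libraries, a horizontal line for the group mean and bars of 1 SD (n = 2). NONMMUG014782.2 and NONMMUG013433.2 were at 0 in db-sham, and NONMMUG073606.1 and NONMMUG014452.2 were at 0 in wt-CLP.

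Many genes set db-CLP apart from both other groups. The series holds no wt-sham group, so separate effects of CLP and of the db state cannot be told from an effect of the 2 combined. The numbers that set each group apart cannot be ranked, since the 3 groups share 1 estimate of spread per gene. The biological coefficient of variation was 34.2% in db-CLP, 22.6% in wt-CLP and 24.8% in db-sham, so calls with db-CLP may be favoured. With only the 4 libraries compared, db-CLP had 417 calls against db-sham and 225 against wt-CLP, and wt-CLP had 291 against db-sham. Of the genes called in both comparisons of db-CLP with all 6 libraries, 102 were higher in db-CLP than in db-sham and in wt-CLP, 73 were lower than in both, and 2 went in opposite directions. NONMMUG038962.2 was among those lower in both, with 216 ± 29.5 CPM in wt-CLP (SD, n = 2). NONMMUG014782.2 was among those higher in both, with 58.8 ± 32.1 CPM in wt-CLP. Independent lists of these lengths would share 6.88 higher and 5.09 lower genes. Simulated unchanged libraries shared 0, which decides nothing, since they gave only 0.8 and 1.4 calls on average in these comparisons. The 175 genes shared in direction became 72 without wt-CLP replicate 2, 267 without db-CLP replicate 2, 78 without db-sham replicate 1 and 38 without db-sham replicate 2.

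Across the 7316 genes, which are not independent replicates, the 2 sets of fold changes correlated at 0.616 with a covariance of 0.569. Unchanged groups that share the db-CLP libraries gave 0.448 and a covariance of 0.142 in simulation. With a different db-CLP library in each comparison the correlation was 0.319 or 0.343, depending on which library went to which comparison, and the covariance was 0.363 or 0.379. These 2 sides share no library, so the simulated 0.448, which is for shared libraries, is no reference for them. The correlations that remained argue against shared libraries as the whole cause of the correlation across genes. Part of the shared calls may still come from the db-CLP libraries that both comparisons use. Calls were not made with split libraries, which leave 1 db-CLP library on each side.

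**Figure D4:**
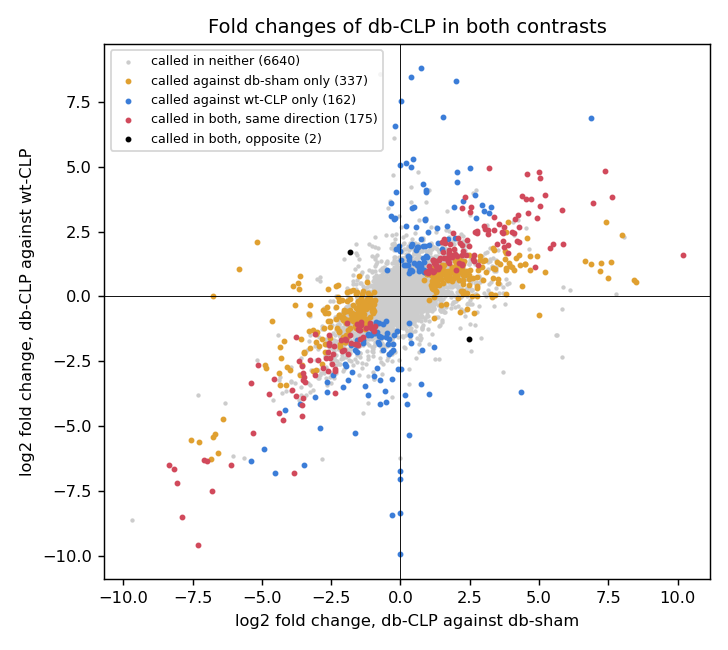
Log2 fold change of db-CLP against db-sham on the horizontal axis and against wt-CLP on the vertical axis, with 1 point per gene tested. The 175 genes called in both with the same direction lie in the lower left and upper right, and 2 genes called in both lie in opposite directions.

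The third comparison, wt-CLP against db-sham, differed in disease state and operation together and gave 66 genes that were higher and 67 that were lower in wt-CLP. The edgeR count of 133 became 376 without db-CLP replicate 1, 338 without db-CLP replicate 2, 51 without db-sham replicate 1 and 23 without db-sham replicate 2. Genes that set db-sham apart from both CLP groups numbered 77, of which 37 were lower and 40 were higher in db-sham. Simulated unchanged libraries gave at most 1 such gene, but they held too few calls for this to decide anything. Independent lists would share 2.45 and 2.22 such genes, and part of the overlap may come from the shared sham libraries. The fold changes correlated across genes at 0.607 against 0.634 in simulated unchanged libraries, with a covariance of 0.556 against 0.232. The 77 became 47 without wt-CLP replicate 1, 168 without db-CLP replicate 1, 177 without db-CLP replicate 2, 28 without db-sham replicate 1 and 9 without db-sham replicate 2.

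Genes that set wt-CLP apart from both db groups numbered 37, of which 15 were lower and 22 were higher in wt-CLP, and 15 further genes were called in both comparisons with wt-CLP between the db groups. Independent lists would share 1.69 and 1.39 genes. Simulated unchanged libraries shared at most 1, but they held too few calls for this to decide anything. The correlation of the fold changes was 0.252 against 0.407 in simulation and the covariance 0.190 against 0.126, and part of the overlap may come from the shared wt-CLP libraries. The 37 became 84 without db-CLP replicate 1, 78 without db-CLP replicate 2, 20 without db-sham replicate 1 and 12 without db-sham replicate 2.

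Each group held 2 libraries, described in the series design as 2 mice per group, and the labels of the libraries say no more about the animals. The p-values of single genes rest on the spread between libraries within groups. For edgeR this spread had 3 residual degrees of freedom and 8.53 prior ones taken from the other genes. The Fisher, Mantel-Haenszel and shuffling p-values were computed over genes and do not measure the spread between mice. The floors cover counting error only.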

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

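Scaling to implied library totals, thinning and whole-count genes were chosen after seeing the data. The counts of 514, 339 and 133 genes (db-CLP against db-sham, db-CLP against wt-CLP, wt-CLP against db-sham) stayed within 1.5 times under RLE and upper-quartile factors, DESeq2, the robust fit, the 2-fold minimum and the implied totals. Under the implied totals the genes themselves changed more than the counts. Of 725, 487 and 138 calls there, 413, 252 and 126 were main calls with the same direction. Limma on log2(FPKM + 1) called 202, 39 and 35, and on log2(FPKM + 0.1) 55, 0 and 0, where limma had 2081, 1566 and 1160 genes at an unadjusted p under 0.05 and DESeq2 called 408, 269 and 177. With the 4 libraries compared alone the counts were 417, 225 and 291. For wt-CLP against db-sham, no filter gave 275, the 50-count filter 86 and whole-count genes 69. Thinning gave 147 for db-CLP against wt-CLP. The cause of these changes was not tested.

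Leaving out 1 library at a time gave 57 to 663, 126 to 441 and 23 to 376 genes. The lowest were without db-sham replicate 2, wt-CLP replicate 2 and db-sham replicate 2, and the highest without db-CLP replicate 2, db-CLP replicate 2 and db-CLP replicate 1. A group left with 1 library is assumed to vary like the others, but the groups did not vary alike: the biological coefficient of variation estimated by edgeR within each pair was 34.2% in db-CLP, 22.6% in wt-CLP and 24.8% in db-sham. Of the 191 genes called between db-CLP and db-sham without db-sham replicate 1, 177 were among the 514 with the same direction. No call changed sign under the settings run, apart from 2 genes of db-CLP against db-sham without db-sham replicate 2.

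With the replicate block the counts were 484, 325 and 148. The numbers share no more than a label, since deviations of libraries with the same number correlated at -0.0087, 0.068 and -0.0094 across genes.

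Over all pairs of a named gene and a setting that tested it, direction and call were kept in 132 and the call was lost in 12, all of them with DESeq2, limma or without db-sham replicate 2. In simulation, with 200 of 7316 genes changed, edgeR called 0% and DESeq2 3% of the genes with a 2-fold change between db-CLP and db-sham. The parts of depth, number of libraries, spread and number of changed genes were not separated. The adjustment is less strict where more genes change, so these shares need not hold for the data. Tests of the fixed gene lists, with their alternatives, were not run because no list member could be matched to an ID.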

Other observations

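The tests below were written before their results were seen. Exceptions are the correlations by distance between ID numbers and the counts of calls tested or kept at equal depth, which were chosen afterwards.

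A small set of genes was present or absent by group. Present means at least 10 CPM in every library. In wt-CLP, 3 genes were at 0 in both libraries and present in the other 4, and 5 were present only there. For db-CLP these numbers were 4 and 2, and for db-sham 4 and 1. The totals of 8, 6 and 5 became 10, 9 and 15 without db-sham replicate 1.

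The 8 genes of wt-CLP part it from db-CLP and db-sham alike. Chance zeros at this depth are argued against, since 20 simulated sets of unchanged libraries gave at most 0 such genes. A different genetic background of the wt and db mice may also part them. Such genes also set apart db-CLP (6) and db-sham (5), which are both db, so having them is not particular to wt-CLP. Of the 8, 2 lay within 20 ID numbers of each other, where 1000 random sets matched on abundance had 0.032 on average and at most 2. This decides nothing on background, since consecutive IDs also had like fold changes between the 2 db groups (correlation 0.351). Background and disease state cannot be told apart here, because the labels name no strain and each disease state is a different set of mice. An effect of the db state itself stays open and was not tested.

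Genes with consecutive ID numbers tended to have like fold changes between groups. Whether they also differ alike between the 2 libraries of a group was not tested, so the pattern is not tied to the group differences. In db-CLP against wt-CLP the fold changes of 1173 such pairs correlated at 0.296, and shuffling genes within 10 strata of abundance gave at most 0.115 (permutation p = 0.001, the smallest that 1000 shuffles give), so similar abundance alone is argued against. The 379 pairs with whole counts correlated at 0.417, which argues against reads split between overlapping gene models as the whole cause. The correlation was 0.198, 0.0875, 0.178 and 0.0322 at gaps of 2, 3, 5 and 10, not a steady fall, and for db-CLP against db-sham it was 0.351 at a gap of 1 and then 0.236, 0.162, 0.0824 and 0.0177. A candidate explanation is shared regulation of neighbouring genes, but whether the ID order follows the genome is not given in the sources used here, and no position was tested.

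The genes called between db-CLP and db-sham rest on a sham group with 1 shallow library. A difference in depth is argued against as the whole cause, since 59.9% of the 514 calls (308) kept call and direction after all libraries were thinned to equal depth, and 277 to 313 did in 10 further draws. Of the 514, 394 could be tested at equal depth. Thinning leaves the shallow library itself as it was, so it cannot clear the calls that rest on that library. The low depth of that library stays open for all calls that were not also made without it. The median log2 difference of db-CLP from that library was 81.6% of that from the deeper one over the 191 genes called without it, which decides nothing, since those genes were chosen without it. A gene length bias in 1 direction is argued against by the rank correlation of -0.0340 between length and fold change across genes. A length effect on higher and lower genes alike would not show in this correlation, which cannot decide on it. An effect of CLP in db mice remains a hypothesis that may account for these genes, with other differences between the 2 pairs of mice untested.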
